A study of Mus musculus with 21 samples.

How the data were processed

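The series asks what apolipoprotein E (ApoE), the main lipid carrier protein of the brain, does to the RNA of microglia, the resident macrophages of the brain. RNA of 21 libraries was analysed in 2 tables. The genotype table holds 7 libraries labelled as wild-type C57BL/6 females and 4 libraries labelled as females of B6.129P2-Apoetm1Unc/J, a strain in which the Apoe gene was disrupted by targeting. The injection table holds 10 libraries labelled as males of that knockout strain, 5 after an injection of phosphate-buffered saline (PBS) into the brain and 5 after an injection of recombinant APOE protein (rAPOE) dissolved in PBS. Per the labels' protocols, the mice were 12 to 18 weeks old, the left hemisphere was injected, microglia were taken 16 h later, and both hemispheres were collected. The labels do not say which hemisphere a library came from, nor that libraries of a group came from separate mice, so p-values measure the spread between these samples, part of which may be technical.

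Per the labels' protocols, total RNA was made into QuantSeq 3′ FWD libraries, which give a tag near the 3′ end of each polyadenylated transcript, and was read on an Illumina MiniSeq. Per the submitters' processing notes, HTSeq, DESeq2, Picard 1.8.4, R 3.2.3 and the mouse genome GRCm38.p3 were used, with no role or order stated. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. The values the authors deposited are a signal per gene, here called the normalised count, in which each library's read count is divided by a library-wide factor. Each table was normalised apart, so no test spans both, and levels are not compared between them. In each library the values above 0 were whole multiples of a fixed step, 100% of them within 0.01 of a whole number of steps, so the read count behind each value could be recovered as value divided by step. Recovered reads came to 2016972 to 3054976 per wild-type library, 4247865 to 4969287 per knockout library, 704225 to 1347501 per PBS library and 857059 to 1119059 per rAPOE library. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

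The genotype table has 18221 entries, of which 22 carry spreadsheet dates in place of a gene name (0.0966% of the summed values) and 120 are 0 in all of its libraries. These were left out, which kept 18079 genes. The injection table has 13297 genes, all kept. All 21 value columns were used. Positions and gene types come from GENCODE M21 for GRCm38, in which 99.3% of the symbols of the genotype table and 99.9% of those of the injection table were found. Counts of genes with near-identical copies or many pseudogenes, such as Hba-a1, Fth1, Mif and the ribosomal proteins, are uncertain, because the handling of shared tags is not stated.

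Values were analysed as log2(normalised count + 1) in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend), for genes with a mean of at least 10 over the libraries of the table. Differences are on that scale, which understates the change of low genes, and are given with the standard error (SE) of the moderated fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The Apoe transcript was also tested by an exact two-sided permutation test. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, for lists with at least 5 measured members. Camera with an estimated correlation and limma's fry were alternatives. All list p-values are Benjamini-Hochberg adjusted over the lists of a table. Counts of members are given over all genes tested and, for some lists, also adjusted over the list alone. Where nothing is said, a count is over all genes tested. The fold changes of both tables were compared across genes by Pearson's r and Spearman's rho, with a p from 100 draws that relabelled the samples of each table. Where all libraries of a group were at 0, the fold is a bound computed at 3 reads over the group.

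The tests, the 41 gene lists and the rule for the genes named were fixed before the data were examined. Of the lists, 38 are pathways or cell types, and the others hold the neighbours of Apoe, the Y-linked genes and the X inactivation genes. The rule named, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among those that passed, leaving out unnamed gene models and pseudogenes, then up to 4 passing members of each list by adjusted p, then up to 10 genes that passed in both comparisons. Other genes named below are list members given with their values, or were chosen after their values were seen, which is said there. The design had foreseen raw counts or normalised counts, and the values were of the normalised kind, so limma was used as written for that case.

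On simulated counts drawn at the real means and depths, limma recovered 72% of 8-fold and 15% of 2-fold changes in the genotype design (9982 genes), with 3 false calls among 90. In the injection design (6526 genes) it recovered 67.4% of 8-fold and 7.07% of 2-fold changes, with 6 false calls among 77. DESeq2 gave 21.3% and 21.7% false calls in these simulations. Alternatives were a pseudocount of 0.5 or 5, no filter or a mean of at least 50, TMM or quantile rescaling, robust moderation, library weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, the replicate number as a block, wild-type libraries 1 to 4 only, and each library left out in turn. Further alternatives chosen after seeing the data were a term for replicates 1 to 3 against 4 and 5 of the injection table, either set alone, leaving out replicate 5 of both injection groups or giving these libraries a term, and quantile rescaling for the lists. Tables were read and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was excluded from the main tests. The wild-type libraries other than 8 were far closer to each other than the libraries of other groups, with an edgeR biological coefficient of variation of 15.7% against 72.5% in the knockout, 47.4% after PBS and 49.3% after rAPOE, and correlations of 0.911 to 0.935 in log2 values. The data do not show whether these 6 came from separate samples, and all were counted as replicates.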

Results

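Microglial RNA was profiled as 3′ tags in libraries labelled as wild-type females (n = 7), ApoE knockout females (n = 4), knockout males injected with PBS (n = 5) and knockout males injected with rAPOE (n = 5). The wild-type libraries other than 8 held 11 to 36 Y-linked reads and Xist at 1127 to 1279, against 0 reads and 1980 to 3292 in the knockout libraries. Markers of sex thus differ between these groups. PBS library 5 and rAPOE library 5 held Xist and no Y-linked reads. The first pair of groups compares brains with and without ApoE, and the second PBS with the protein, 16 h after injection into a brain that lacks it. Wild-type libraries held 2016972 to 3054976 reads and 13592 to 15248 detected genes. Knockout libraries held more reads, 4247865 to 4969287, over fewer genes, 8117 to 10479. PBS and rAPOE libraries held 704225 to 1347501 reads over 7601 to 11342 genes.

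Apoe, on the minus strand of chromosome 7 at 19696109 to 19699188 (GRCm38), was the gene the strain was made to lack. Its normalised count was 12573 ± 5263 (SD, n = 7) in wild-type and 8.32 ± 10.9 (SD, n = 4) in knockout libraries, 1512-fold lower in the knockout. The knockout libraries held 18, 0, 0 and 52 Apoe reads, and a library with 0 reads allows a level of up to 1.34. On the log2 scale Apoe fell by 11.25 (SE 0.91, limma adjusted p = 1.58e-06; exact permutation p = 0.00303 over 330 splits, two-sided, the smallest possible). Wild-type library 8 stood apart at 1011, against 13195 to 17163 in the other wild-type libraries, and was still 122-fold above the knockout mean. The allele is disrupted in the middle of the gene, and 3′ tags come from the last exon outside the disrupted part, so the level shows how much Apoe transcript remained and not the disruption itself. Apoe stayed at 0 to 1.32 in the PBS and 0 to 8.54 in the rAPOE libraries, the highest being 11 reads in rAPOE library 4.

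Relative counts of genes that mark resting microglia were higher in the knockout libraries. The same libraries held fewer detected genes, far less RNA of the choroid plexus, neuron and astrocyte markers given further on, and a lower share of mitochondrial ribosomal RNA (0.647% to 0.886%, against 1.36% to 1.59% in the wild-type libraries other than 8 and 4.67% in library 8). Of 30 measured members of the homeostatic list, 14 rose and 1 fell (16 and 1 adjusted over the list alone, 21 and 1 without wild-type library 8). The median log2 change was 0.46, which is 0.91 above the median of all genes. That median depended on level, at −1.21 for means of 10 to 50, −0.18 for 50 to 500 and 0.10 for 500 or more. For abundant lists of the knockout comparison, offsets from all genes and camera p-values may thus partly reflect level. Tmem119, a microglial membrane protein, rose from 2097 ± 267 (SD, n = 7) to 4915 ± 443 (SD, n = 4), by 1.23 on the log2 scale (SE 0.13, limma adjusted p = 1.18e-05). Fcrls, an Fc receptor-like scavenger receptor, rose by 0.89 (SE 0.13), and Selplg, the P-selectin ligand, by 0.77 (SE 0.14), and for all of these the 4 knockout libraries lay above each wild-type library. P2ry12, the purine receptor that guides microglial processes, rose by 0.79 (SE 0.23, adjusted p = 0.0214) and lost the call without knockout library 1 or 4 (highest adjusted p = 0.0532) and in edgeR (adjusted p = 0.0705). The list passed with camera (adjusted p = 1.19e-10), but not with an estimated correlation (adjusted p = 0.298).

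Surface receptors rose as a group, with 28 of 70 measured members higher and 2 lower (36 and 2 adjusted over the list alone; median 0.58, which is 1.03 above all genes). The tetraspanin Cd53 rose 2.73-fold from 531 ± 70.6 (SD, n = 7) to 1450 ± 147 (SD, n = 4), the interferon-gamma receptor chain Ifngr1 2.80-fold, the organic anion transporter Slco2b1 2.01-fold, and the platelet-activating factor receptor Ptafr 2.30-fold. This was the only genotype list to pass with both the preset (camera adjusted p = 1.37e-18) and the estimated correlation (adjusted p = 2.85e-05). Both lists kept their direction under TMM and quantile rescaling. Neither the offset from all genes nor camera took the level of the genes into account.

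Genes of disease-associated microglia, the state seen around plaques and dying cells, went the other way. Of 38 measured members, 17 fell and 0 rose (20 and 2 adjusted over the list alone; median −0.98). Lpl, the lipoprotein lipase, fell from 1265 ± 567 (SD, n = 7) to 55.9 ± 39.6 (SD, n = 4), and so fell by 4.28 on the log2 scale (SE 0.80, limma adjusted p = 0.00133). Fabp5, a fatty acid binding protein, fell from 88.0 ± 35.8 to 2.70 ± 5.39, the growth factor Igf1 from 283 ± 125 to 7.95 ± 15.9, and the actin-capping protein Capg from 84.6 ± 33.1 to 5.33 ± 7.13. Fabp5 and Igf1 had reads in knockout library 1 alone among the knockout libraries. Wild-type library 8 was far below the other wild-type libraries for all of these genes, with 54.2 for Lpl, 10.8 for Fabp5, 7.22 for Igf1 and 16.2 for Capg. Without that library 28 members fell and 3 rose, and the list had a camera adjusted p of 4.49e-08. With all libraries it passed narrowly (camera adjusted p = 0.0301), not with an estimated correlation (adjusted p = 0.726), and not without wild-type library 2 (0.0542), knockout library 2 (0.106) or knockout library 4 (0.0902).

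Genes of alternatively activated and glioma-associated microglia overlap that list, and 15 of 32 fell while 0 rose (median −1.67), though the list did not pass (camera adjusted p = 0.0546, and 0.685 with an estimated correlation). Under quantile rescaling 11 fell, the median was −0.56 and the list passed (camera adjusted p = 0.0152). It also passed without wild-type library 8 (0.0144, 17 lower and 1 higher) or knockout library 1 (0.0356). Csf1, the macrophage growth factor, was 12.1-fold lower. The secreted protein Spp1 fell from 108 ± 45.4 to 6.01 ± 7.09, and Gpnmb, a lysosomal membrane glycoprotein, from 577 ± 288 to 1.85 ± 3.69 (reads in knockout library 1 alone). Gpnmb was at 0 in wild-type library 8, and Spp1 at 7.22.

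Many genes of the monocyte list fell in the same libraries. Of 22 measured monocyte genes, 14 fell and 1 rose (median −3.50, −3.56 with genes at 0 in the knockout at their bound; camera adjusted p = 0.00157, and 0.639 with an estimated correlation). Under quantile rescaling 10 fell and 2 rose (median −1.37). Fn1, the matrix protein fibronectin, was at 866 ± 381 (SD, n = 7) in the wild type and had 1 read over all knockout libraries. The calcium-binding protein S100a4 was at least 402-fold lower in the knockout, where each library was at 0, and the peptidase Ace was 62.5-fold lower, with reads in knockout library 4 alone (−7.37 to −6.15 on the log2 scale with a library left out). In wild-type library 8, Fn1 was at 16.2, S100a4 at 1.81 and Ace at 46.9, against means of 1008, 164 and 202 in the other wild-type libraries. Alox15, a lipoxygenase, was at least 1358-fold lower in the knockout and at 0 in wild-type library 8. Saa3, an acute-phase apolipoprotein, was 957-fold lower, with reads in knockout library 4 alone (−9.65 to −7.90 on the log2 scale with a library left out), and also at 0 in wild-type library 8. Border macrophage genes (5 of 14 lower, 1 higher) and B cell genes (4 of 10 lower) did not pass as lists (camera adjusted p = 0.0860 and 0.267), though without wild-type library 8 the B cell list did (camera adjusted p = 0.0318, 6 lower).

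Markers of cells outside the immune system fell in the knockout libraries. All 9 measured ependymal and choroid plexus genes fell, with a median of −6.51 (−6.71 with bounds). Ttr, the thyroid hormone carrier made by the choroid plexus, fell from 46330 ± 15863 (SD, n = 7) to 447 ± 177 (SD, n = 4), a 104-fold difference, and the lysophospholipase Enpp2 fell 92.4-fold. The folate receptor Folr1 was at least 919-fold lower, and Sostdc1, a secreted antagonist of bone morphogenetic proteins, at least 854-fold lower. For these choroid plexus genes wild-type library 8 was also below the other wild-type libraries, but far above the knockout (Ttr 16090, Enpp2 6704, Folr1 153, Sostdc1 144). Astrocyte genes fell in 16 of 17 cases (Clu 45.3-fold), neuron genes in 14 of 16 (Map2 at least 488-fold, Syt1 87.3-fold, with reads in knockout library 2 alone and −7.27 to −6.17 on the log2 scale with a library left out), oligodendrocyte genes in 8 of 14, endothelial genes in 7 of 14 (Flt1 3.79-fold), and pericyte and fibroblast genes in 5 of 7 (Col1a2 at least 97.8-fold). Medians were −3.68, −4.54, −3.73, −2.28 and −4.12, and over all genes none of these lists had a member that rose. Adjusted over the list alone, 1 endothelial gene rose and 9 fell. Under quantile rescaling these medians shrank to −2.63, −2.45, −1.36, −0.63 and −1.13, with 12, 10, 6, 4 and 3 members lower and 1 endothelial gene higher. The choroid plexus median became −5.17 with 8 lower. Camera with the preset correlation passed the choroid plexus list (adjusted p = 5.61e-12) and the astrocyte (2.68e-08), neuron (4.10e-07), oligodendrocyte (6.96e-04), endothelial (0.0301) and pericyte (0.00654) lists. None passed with an estimated correlation, with adjusted p of 0.0796, 0.0796, 0.380, 0.432, 0.613 and 0.477 in that order. The endothelial list also missed without knockout library 2 (0.0994) or 3 (0.0525), and under quantile rescaling (0.0932). In the mean log2 values of the astrocyte, neuron, oligodendrocyte, endothelial and pericyte lists wild-type library 8 stood apart from the other wild-type libraries. Its neuron mean was 2.57, with Map2 at 2.68 and Syt1 at 4.11 on that scale, below the others. The falls of neuron genes thus rest more on the other wild-type libraries.

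Among metabolic lists, oxidative phosphorylation had 21 of 48 members lower and 0 higher (31 and 0 adjusted over the list alone; median −0.82), and 34 lower without wild-type library 8. The cytochrome oxidase subunit Cox6a1 was 2.46-fold and the complex I subunit Ndufa4 2.38-fold lower. Cholesterol synthesis and uptake had 10 of 22 lower and 0 higher (13 and 0 adjusted over the list alone; median −1.82), and under quantile rescaling 4 lower and 1 higher (median −0.54). Hsd17b7, a sterol reductase, was at least 77.4-fold lower. Camera gave adjusted p of 2.88e-04 and 0.00714 for these lists, and 0.677 and 0.380 with an estimated correlation. The unfolded protein response list had 4 of 20 higher and 2 lower (7 and 4 without wild-type library 8), with Herpud1, the transcription factor Xbp1 and the chaperone Dnajb9 up by 1.26, 1.07 and 1.70 and the chaperone Hsp90b1 down (−1.07). The lysosome list had 10 of 52 higher and 5 lower, led by the protease Lgmn (0.95) and by Gla, which fell (−4.01, with reads in knockout library 3 alone), and 12 higher and 16 lower without wild-type library 8. The dendritic cell list had 3 of 8 higher and 1 lower, the risers being Irf8, a factor microglia also use, Fscn1 and Batf3, and the ribosomal list had 1 of 53 higher (Rplp1) and 1 lower (Rpl35), or 2 and 17 without wild-type library 8. These lists passed only as higher than all genes (camera adjusted p = 0.0467, 0.0301, 0.0467 and 0.0301), with medians of −0.16, −0.05, 0.26 and 0.45 above all genes for the last, means of −0.03, −0.21, −0.28 and −0.04, and adjusted p of 0.294, 0.721, 0.325 and 0.726 with an estimated correlation. Without wild-type library 8 none of these passed (adjusted p = 0.0909, 0.587, 0.0850 and 0.702), and quantile rescaling ended these calls as well (0.540, 0.605, 0.120 and 0.923). The test of the ribosomal list leaned downward in both cases. The unfolded protein response call was also lost without wild-type library 2 (0.0568), 4 (0.0544) or 7 (0.0502) and knockout library 1 (0.0695), 2 (0.0791) or 3 (0.0580), and the dendritic call without wild-type library 2 (0.0542) or 4 (0.0552) and knockout library 1 (0.0626), 2 (0.0994) or 4 (0.0665). The lysosome call was lost without knockout library 3 (0.0525) or 4 (0.0519), and the ribosomal call without knockout library 1 (0.0578) or 3 (0.0607).

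**Figure D1:**
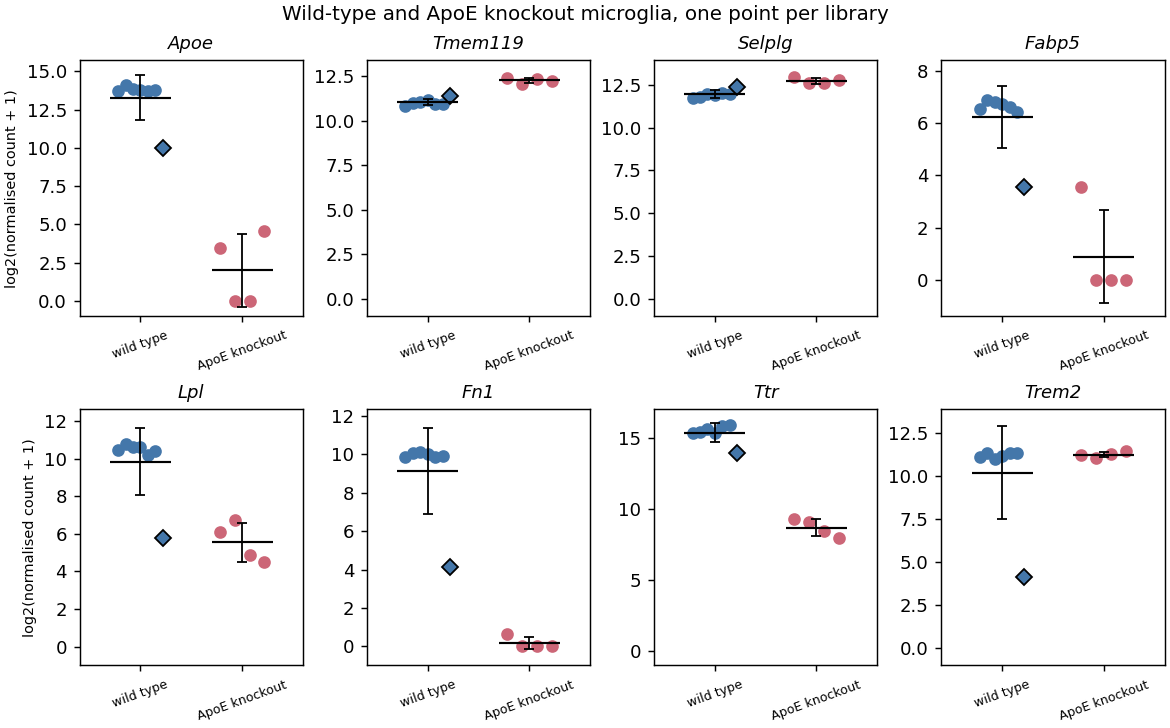
Points are single libraries of wild-type (blue, n = 7) and ApoE knockout (red, n = 4) microglia, with the mean (line) and SD (bar) of log2(normalised count + 1) on the vertical axis, and the black-edged diamond is wild-type library 8. Tmem119 and Selplg were higher in each knockout library, Fabp5 and Lpl were lower with wild-type library 8 near the knockout, Fn1 and Ttr were lower with that library between the knockout and the other wild-type libraries, and Trem2 was at 16.2 in that library alone.

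Over all genes, 2596 of 10401 tested passed, 535 higher and 2061 lower in the knockout. The largest rises were small in level. They included the spliceosomal RNA Rnu11 (3.46, SE 0.48), Lrmda (2.81, SE 0.60), mt-Nd3 (2.80, SE 0.77, but edgeR adjusted p = 0.0762), R74862 (2.77, SE 0.54), Map10 (2.69, SE 0.74), the C-type lectin-like gene BC035044 (2.17, SE 0.28) and the anion transporter Slco4a1 (2.08, SE 0.53). The largest falls after Apoe were Fn1 (−8.97), Folr1 (−8.27), Saa3 (−8.19), Sostdc1 (−8.16), Gda (−8.14), Cgnl1 (−8.08), Atp2b3 (−7.92), Alox15 (−7.81), Nsg2 (−7.71), Slco1c1 (−7.58) and the anti-ageing hormone Kl (−7.54, with reads in knockout library 4 alone), several of them genes of the choroid plexus and macrophage groups above. Of the 2061 lower genes, 482 had 0 reads in all knockout libraries. The median of all genes lay at −0.45, and quantile rescaling moved it to 0.09 and the split to 920 higher and 1027 lower. edgeR on recovered reads passed 1657 genes (498 higher, 1159 lower), and a mean of at least 50 left 1289 (488 higher, 801 lower).

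In knockout males, some inflammatory and interferon-response genes were higher after rAPOE than after PBS. Of 33 measured inflammatory and NF-kB genes, 7 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 1.51. Saa3 rose from 0.418 ± 0.593 (SD, n = 5) after PBS to 202 ± 117 (SD, n = 5) after rAPOE, by 7.05 on the log2 scale (SE 0.82, limma adjusted p = 7.68e-05). The chemokine Ccl5, which recruits T cells and monocytes, rose from 8.53 ± 10.3 to 356 ± 170, by 5.82 (SE 0.72, limma adjusted p = 1.18e-04). The chemokines Cxcl10, Ccl12 and Cxcl16 rose 8.31-fold, 5.80-fold and 4.48-fold, the mitochondrial superoxide dismutase Sod2 4.99-fold, and the lipopeptide receptor Tlr2 2.84-fold. In each of these 7 genes all 5 rAPOE libraries were above all 5 PBS libraries. The cytokines Tnf (123 ± 58.9 to 382 ± 225, adjusted p = 0.0998), Il1b (56.5 ± 25.2 to 253 ± 215, adjusted p = 0.155) and Ccl2 (41.5 ± 37.4 to 220 ± 150, adjusted p = 0.0789), chosen after their values were seen, did not pass.

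Interferon-response genes showed a median of 1.52, and 3 of 28 rose (10 adjusted over the list alone, 0 lower in either count). Without both libraries numbered 5, 1 rose and the median was 1.06. Of the inflammatory genes 6 then rose, with a median of 1.29. The 3 that rose with all libraries were Cxcl10, the ubiquitin-like protein Isg15 (3.76 ± 4.60 to 87.6 ± 54.0) and the antiviral membrane protein Bst2 (91.6 ± 28.6 to 310 ± 137). Both lists passed with camera (adjusted p = 9.04e-17 and 1.92e-11) and both had an adjusted p of 0.0659 with an estimated correlation. Ifitm3, an interferon-induced membrane protein counted here among the monocyte genes, rose 9.81-fold (3.28, SE 0.35, limma adjusted p = 3.22e-05). Of 7 monocyte genes, 2 rose and 0 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.0320, and 0.137 with an estimated correlation). That monocyte call was lost without PBS library 2 (0.0926) or rAPOE library 1 (0.0756), 2 (0.0674) or 5 (0.144), and without both libraries numbered 5 (0.105). The scavenger receptors Marco (3.49 ± 6.43 to 131 ± 84.5) and Msr1 (91.7 ± 33.1 to 441 ± 236) were the 2 risers among 18 measured genes of alternative activation, with 0 lower. Adjusted over the list alone, 3 were higher and 1 lower. The list passed (camera adjusted p = 0.0203, and 0.324 with an estimated correlation), a call lost without PBS library 1 (0.203) or rAPOE library 4 (0.0996) or 5 (0.0800). Other genes with large rises were the dicarboxylate transporter Slc13a3 (4.89), the lectin receptor Clec4a1 (4.76), the superoxide-generating oxidase subunit Cybb (4.23), the B cell co-receptor Cd72 (2.97) and the Fc receptor Fcgr4 (2.43).

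Homeostatic genes fell after rAPOE, with 4 of 30 lower and 0 higher over all genes and 21 lower and 0 higher adjusted over the list alone (median −0.83). P2ry12 fell from 1428 ± 159 (SD, n = 5) to 494 ± 360 (SD, n = 5), by 1.77 on the log2 scale (SE 0.31, limma adjusted p = 0.00663), and Selplg from 1500 ± 179 to 600 ± 185, by 1.38 (SE 0.24, limma adjusted p = 0.00605). The purinergic-like receptor Gpr34 fell 2.50-fold and the sialic acid receptor Siglech 2.56-fold. Without both libraries numbered 5, 0 of the 30 genes passed over all genes (median −0.72), though the list still passed with camera, and in edgeR P2ry12 (adjusted p = 0.0649), Gpr34 (0.148) and Siglech (0.0556) missed. The list passed with camera (adjusted p = 2.75e-22) and with an estimated correlation (adjusted p = 0.0472). Lysosome genes lay lower as a list (48 measured, 0 lower and 0 higher over all genes, 6 and 1 adjusted over the list alone, median −0.30; camera adjusted p = 4.06e-05, and 0.0435 with an estimated correlation). Glycolysis and hypoxia genes lay higher (21 measured, 1 higher, median 0.89; adjusted p = 7.25e-05 and 0.0435). The member that rose, Mif, is a macrophage cytokine and not a glycolytic enzyme, and Ldha (1.22, SE 0.45), chosen after its value was seen, did not pass alone. Oxidative stress and Nrf2 targets had 3 of 22 higher, Sod2, Cybb and the ferritin heavy chain Fth1 (2.64-fold; median 0.54, camera adjusted p = 7.25e-05, and 0.130 with an estimated correlation). Oxidative phosphorylation (median 0.50) and ribosomal (median 0.39) lists passed as higher (camera adjusted p = 1.67e-05 and 5.26e-08) with 0 members passing over all genes (1 ribosomal gene higher adjusted over the list alone) and adjusted p of 0.226 and 0.465 with an estimated correlation. Dissociation and immediate early genes lay lower (median −0.33, camera adjusted p = 0.0114, and 0.465 with an estimated correlation), with 1 of 35 falling, the antiproliferative gene Btg2. Adjusted over the list alone, 3 were higher and 10 lower. The list lost the call without PBS library 4 (0.128) or rAPOE library 2 (0.0971).

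**Figure D2:**
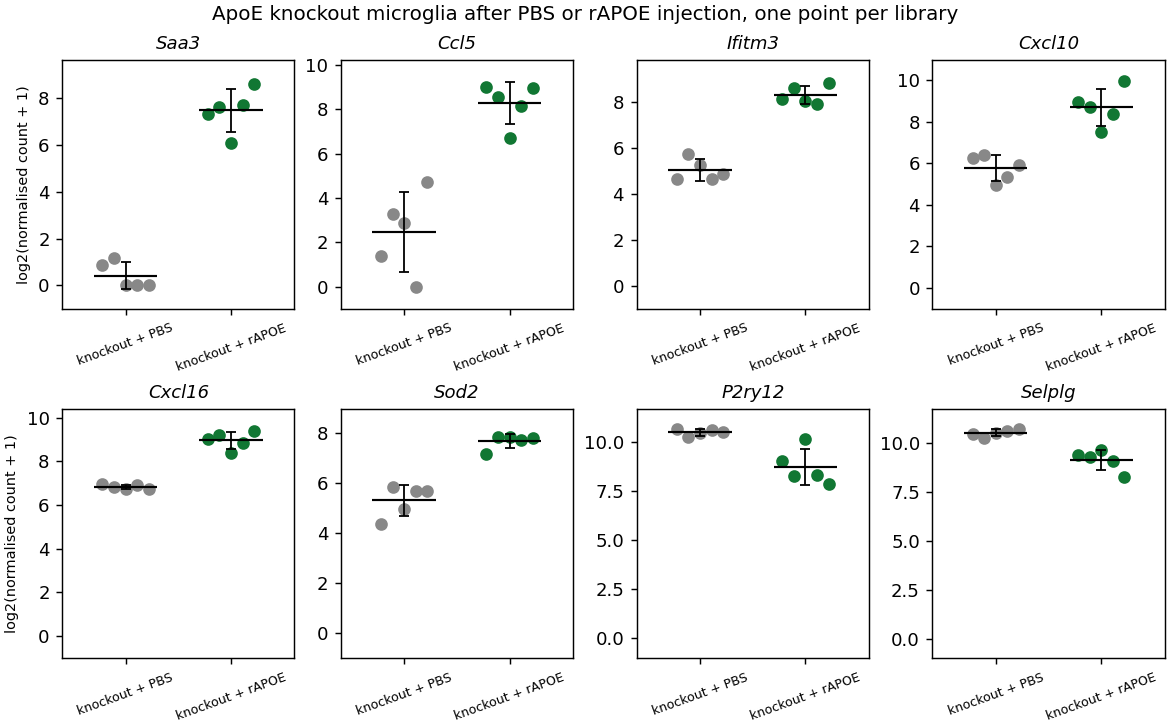
Points are single libraries of knockout microglia after PBS (grey, n = 5) or rAPOE (green, n = 5), with the mean (line) and SD (bar) of log2(normalised count + 1) on the vertical axis. All 5 rAPOE libraries lay above all 5 PBS libraries for Saa3, Ccl5, Ifitm3, Cxcl10, Cxcl16 and Sod2, and below them for P2ry12 and Selplg.

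Over all genes, 34 of 7066 tested passed, 26 higher and 8 lower, and 792 had an unadjusted p under 0.05. The other falls were the B cell survival receptor Tnfrsf13b (−1.73), the integrin chain Itgb5 (−1.22), the sialomucin Cd164 (−1.17) and Btg2 (−1.07). Replicates 1 to 3 and 4 to 5 differed in detected genes in both groups (7601 to 8837 against 10025 to 11342), and each set holds as many PBS as rAPOE libraries. A term for that split gave 73 genes (44 higher, 29 lower), all 34 among them, replicates 1 to 3 alone gave 6 (5 higher, 1 lower) and replicates 4 and 5 alone 192 (110 higher, 82 lower). PBS library 5 and rAPOE library 5 carried Xist and no Y-linked reads although labelled male, and without both 11 genes passed (10 higher, 1 lower). All 34 kept their direction there. A term for these libraries, with all libraries kept, gave 33 genes (24 higher, 9 lower), 31 of the 34 among them. The count was 22, 20 and 16 without rAPOE library 1, 2 and 5, and 74 without rAPOE library 3 (36 higher, 38 lower). The split also turned on the method, with 23 higher and 1 lower in edgeR, 137 and 127 with library weights, and 66 and 48 in DESeq2. Saa3, Ccl5, Ifitm3, Cxcl10, Ccl12, Cxcl16, Sod2, Tlr2, Fth1, Marco, Cybb, P2ry12 and Selplg passed with each library left out in turn, while Clec4a1, Gpr34, Itgb5, Tnfrsf13b, Siglech, Cd52, Mif, Cd164, Btg2 and Ms4a6c passed in 1 to 4 of the 10 such fits.

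Whether the protein moved genes against the direction of its loss was asked by comparing both sets of log2 changes, which share no library and come from libraries labelled female without injection and labelled male with it. The Xist and Y-linked reads above do not fully bear out these labels. Fisher's exact test counts genes as independent, which they are not, so its p-values for the overlaps below do not measure the spread between samples. Of the genes tested in both tables, 5 rose in the knockout and fell after rAPOE (Btg2, Cd164, Gpr34, P2ry12 and Selplg), where independent lists would share 0.591 (Fisher's exact test, adjusted p = 4.02e-04 over 4 overlaps). Only 2 of them, P2ry12 and Selplg, were shared without PBS library 1, 3 or 4 or rAPOE library 2, 4 or 5, and 3 genes without PBS library 5 or rAPOE library 1, while 6 were shared without PBS library 2, 16 without rAPOE library 3, and 4 (not P2ry12) without knockout library 1 or 4. The overlap missed the threshold without rAPOE library 4 (Fisher's exact test, adjusted p = 0.0944). Conversely 7 fell in the knockout and rose after rAPOE (Ccl5, the carboxypeptidase Cpd, Cybb, Ifitm3, Marco, Msr1 and Saa3), where 2.85 would be shared (Fisher's exact test, adjusted p = 0.0370). That overlap missed the threshold without wild-type library 1 (0.0973), 2 (0.104), 3 (0.103), 4 (0.115), 6 (0.104) or 7 (0.103), without knockout library 1 (0.117), 2 (0.482), 3 (0.103) or 4 (0.409), and without rAPOE library 3 (0.115), with 5 to 8 genes shared. In the knockout comparison Ccl5 missed in edgeR (adjusted p = 0.340) and without knockout library 2 or 4, and Msr1 missed in edgeR (0.0547). Cpd and Cybb were not shared without wild-type library 1, 2, 3, 4, 6 or 7. Only 1 gene rose in both (Ms4a6c; 1.85 for independent lists, adjusted p = 1) and 0 fell in both (0.912, adjusted p = 0.812), while without rAPOE library 3 these were 4 (Adgre1, Ctsc, Ms4a6c and Ms4a6d) and 1 (P2ry13), with neither overlap passing. Of the 7, Saa3 and Marco were at 0 and Msr1, Ccl5, Ifitm3 and Cybb at 3.61, 3.61, 27.1 and 18.1 in wild-type library 8, below the knockout means. As a set, the 508 genes higher in the knockout lay lower after rAPOE (338 below 0, median −0.31; camera adjusted p = 4.05e-06, and 0.0359 with an estimated correlation). The 783 genes lower in the knockout lay higher after rAPOE by camera (439 above 0, median 0.11; adjusted p = 0.0213), though not with an estimated correlation (adjusted p = 0.330). The 8 genes lower after rAPOE lay higher in the knockout (7 above 0; adjusted p = 1.09e-05, and 0.0423 with an estimated correlation), and the 25 higher after rAPOE were not called in either direction (adjusted p = 0.917; their median was −0.57 while the test leaned upward).

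Across 6871 genes, which are not independent replicates, the log2 changes were weakly and inversely related (r = −0.14, permutation p = 0.0099, the smallest 100 draws can give; rho = −0.14, permutation p = 0.0396). The relation missed that level without rAPOE library 4 (r = −0.10, permutation p = 0.0792) or 5 (r = −0.10, permutation p = 0.0693), under quantile rescaling (permutation p = 0.0792), and with a mean of at least 50 (r = −0.26, permutation p = 0.0693).

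**Figure D3:**
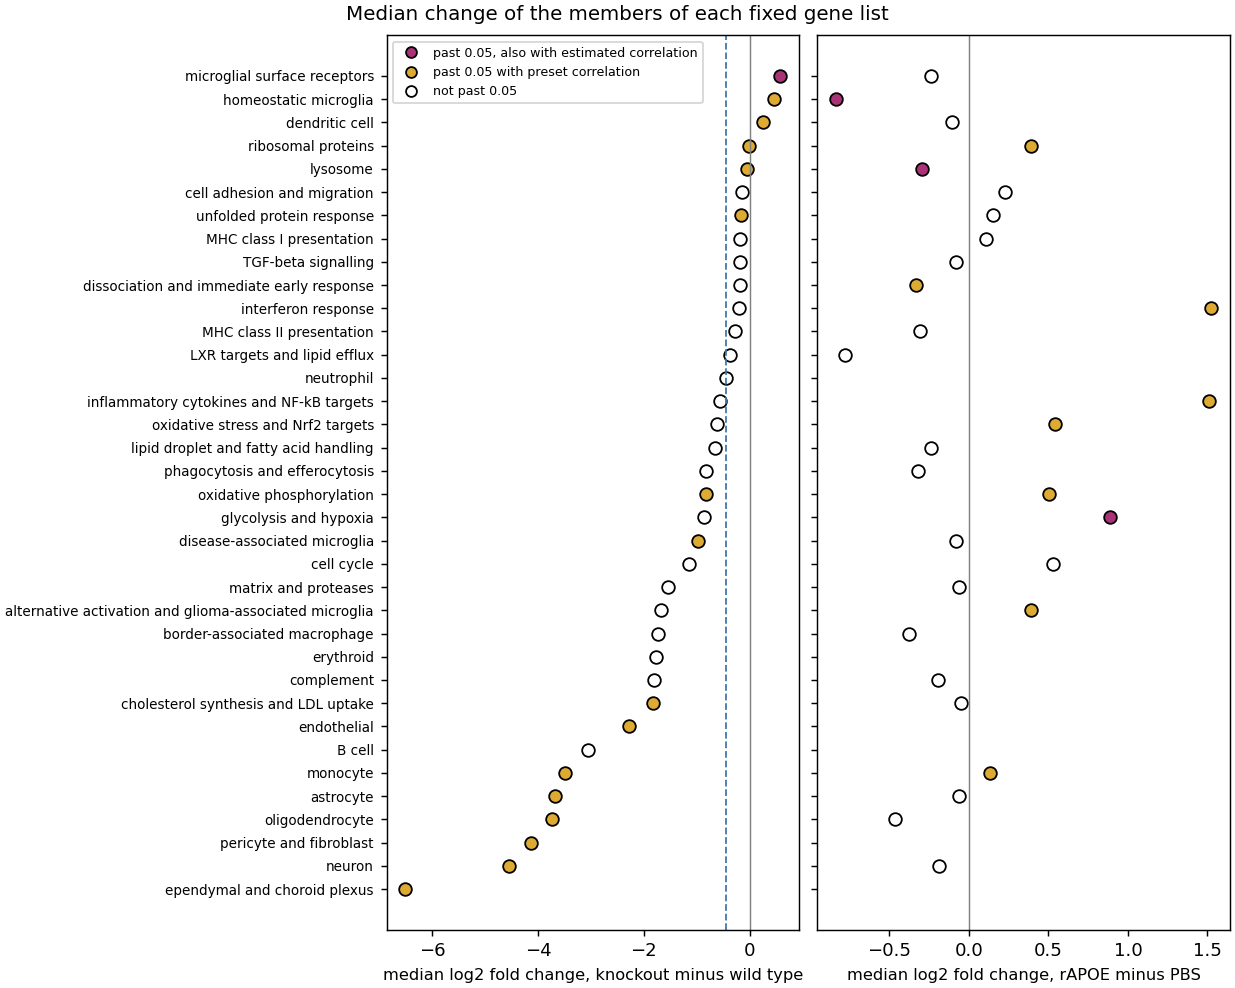
Each point is the median log2 change of the measured members of a gene list, knockout minus wild type on the left and rAPOE minus PBS on the right. The dashed line, on the left only, is at the median of all genes of the knockout comparison (−0.45). Filled points passed camera at an adjusted p of 0.05, purple ones also with an estimated correlation. Homeostatic genes lay at 0.46 in the knockout and at −0.83 after rAPOE, and choroid plexus genes lay lowest in the knockout at −6.51.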

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

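The tests of the loss of ApoE, of infiltrating neutrophils and monocytes and of Trem2, and the term for the replicate sets, were chosen only after their results were seen. The minimum of 5 transcripts with a mean of at least 10 for judging infiltration was also set after seeing the values.

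Many macrophage genes were far higher in the wild-type libraries other than 8 than in the knockout, and most choroid plexus genes were so in all 7, though not every macrophage gene was absent from the knockout (Lyz2 at 654, against 164 in wild-type library 8). RNA of other cells in the wild-type libraries is a candidate source, and a larger share of microglial RNA in the knockout libraries may then also raise the homeostatic genes, while fewer distinct molecules in the knockout libraries stay open for the low genes. Of 9 further serosal macrophage markers, 7 were measured and 100% were lower in the knockout without wild-type library 8, against 22.6% of all genes, with means of 303 for Lbp, 281 for Wfdc17 and 226 for Emilin2 in the other 6 wild-type libraries. Of 14 further choroid plexus markers, 13 were measured and 100% were lower, against 19.8% of all genes (Prlr 671, Tmem72 300.1, Aqp1 254), and the fixed lists held 0 genes of either set. A marker counted as measured if it was tested and had a mean of at least 10 in the wild-type libraries compared. Markers high there were thus let in, which favours lower ones, so 100% overstates the contrast with all genes. The markers left out, Rarb, Cav1 and Krt8, were at 0 in the knockout and at 3.41, 10.5 and 4.18 in the wild type. If loss of ApoE lowered the disease-associated genes, wild-type library 8 was foretold to lie nearer to the other wild-type libraries than to the knockout in most lower members. It did so in 0 of 17 (0%), so that prediction was not met. A single library excludes nothing, however, so the loss of ApoE itself stays open for these genes.

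After rAPOE 7 of 33 inflammatory and 3 of 28 interferon-response genes rose, and both lists passed with camera but not with an estimated correlation (adjusted p = 0.0659). Replicates 1 to 3 and 4 to 5 hold both groups in equal numbers, and with a term for these sets 73 genes passed, all 34 among them. Infiltrating neutrophils and monocytes stay open. The 6 neutrophil transcripts had a median log2 change of −0.52 and the 8 monocyte transcripts of 0.40. The standard errors of the mean over transcripts were 0.41 and 0.27, which do not measure the spread between libraries. Only 3 and 2 of these transcripts reached a mean of 10 (S100a8 29.5 and Lyz2 175 after rAPOE), and all of them are also in the fixed lists. A response to APOE protein and a response to anything that came with the preparation, such as endotoxin, may both give this pattern, and no sample here separates them.

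Wild-type library 8 stood apart, with 30 of 36 gene lists and 72 of 153 named genes far from the other wild-type libraries, where chance would set apart about 1 in 20 groups. Its log2 values correlated at 0.703 to 0.730 with the other wild-type libraries and at 0.650 to 0.737 with the knockout, while the other wild-type libraries correlated at 0.911 to 0.935 with each other. Trem2, chosen after its value was seen, had 9 reads in it, 145-fold below the mean of the other wild-type or of the knockout libraries, whichever was lower. Trem2 itself was the only 1 of 186 abundant genes at least 16-fold lower there than in both sets. A loss of that size shared by many abundant genes is thus argued against as the source of the low Trem2. An even loss of molecules across the library would be scaled out by the normalisation, so this count cannot decide on it. A mislabelled sample, for instance from a mouse lacking Trem2, may explain both Trem2 and the low disease-associated genes (0% of lower members nearer to the wild type), but no sample here tests it, and a difference between animals stays open as well.

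In wild-type library 8 the ribosomal-repeat transcript Gm42418 took 42.1% of reads (95% Wilson interval 42.0% to 42.1%), against 15.6% to 19.8% in the other wild-type libraries. Mitochondrial ribosomal RNA took 4.67% there (4.64% to 4.70%), against 1.36% to 1.59%. Apoe stood apart in that library at 1011 and Xist at 3291. Apoe stood apart in rAPOE library 4 at 8.54. Xist was at 979 in PBS library 5 and at 718 in rAPOE library 5, both labelled male, and the Y-linked sum of rAPOE library 5 was 0. Of the libraries labelled female, wild-type libraries 1, 2, 3, 4, 6 and 7 held 29, 11, 34, 25, 19 and 36 Y-linked reads, while wild-type library 8 and the 4 knockout libraries held 0. Among the library-wide measures, 8 of 28 groups had a library apart.

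Among gene lists, knockout library 1 stood apart in 2 (homeostatic and erythroid), knockout library 3 in 1 (phagocytosis), knockout library 4 in 1 (neutrophil) and PBS library 2 in 1 (LXR targets, of 30). Among named genes, knockout libraries 1, 2, 3 and 4 stood apart in 13, 8, 4 and 10 and wild-type library 1 in 1 (Hsp90ab1). In most of these knockout cases the other knockout libraries were tied, as for Fabp5 and Igf1, which had reads in knockout library 1 alone. Such ties do not mark a library as unusual, and the chance rate given above does not hold for them. Of 29 named genes of the injection comparison, PBS library 1 stood apart in 1 (Clec4a1), PBS library 2 in 1 (Cybb), rAPOE library 1 in 1 (Sod2) and rAPOE library 5 in 1 (Fcgr4).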

How the results depend on the processing

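The replicate-set term, the replicate subsets, leaving out both libraries numbered 5, quantile rescaling of the lists, and leaving out single libraries for the overlaps of the comparisons were chosen after seeing the data. The fall of Apoe kept its direction and call in all alternatives run (−12.11 to −10.58 with a library left out). The 2596 genotype genes became 1289 with a mean of at least 50, which tests fewer genes, and 1657 with edgeR; the other alternatives gave 1781 (replicate number as a block) to 3669 (no filter), and leaving out a library 2007 to 3169. The 16 genotype lists became 1 with an estimated correlation and 10 with a mean of at least 50. Fry, which asks another question, gave 24 (2 higher, 22 lower), 11 of the 16 among them, and quantile rescaling 16 (3 higher, 13 lower), again with 11. The replicate block gave 16 (2 higher, 14 lower), with 12 of the 16. With a library left out 12 to 16 lists passed, and without wild-type library 8 the split went from 6 higher and 10 lower to 2 and 13, with 12 of the 16 kept. The 34 injection genes became 64 with a pseudocount of 5, 67 under quantile rescaling, 264 with library weights, 114 with DESeq2, 24 with edgeR, 52 with the replicate block, 73 with the replicate-set term, 6 and 192 in replicates 1 to 3 and 4 to 5 alone, 11 without both libraries numbered 5, and 16 to 74 with a library left out. The 11 injection lists became 3 with an estimated correlation, 8 with fry (7 of the 11 among them), and 9 to 11 with a library left out. The correlation of both sets of changes was −0.264 with a mean of at least 50 (permutation p = 0.0693), −0.130 under quantile rescaling (permutation p = 0.0792), and −0.174 to −0.100 with a library left out. Apart from fewer genes or samples, the cause was not tested. Under TMM, edgeR, a pseudocount of 5, the replicate block and libraries left out, none of the named genes changed direction, and edgeR lost the call of 23 of 152 genotype and 9 of 29 injection genes. Replicate numbers were tried as pairs although the labels do not pair them; same-number libraries correlated at −0.0157 to 0.0167 in the genotype and −0.00418 to 0.185 in the injection table, and 2 of 8 and 3 of 10 libraries correlated best with their own number. In the simulations 2-fold changes were recovered in 15% and 7.07% of the changed genes, so many real differences of that size may have been missed. Smaller ones could still pass, since 2047 of the 2596 genotype genes had an absolute log2 change of 1 or more and the others less. The simulations gave a gene the same spread in both groups, while the knockout libraries spread more than the wild-type libraries other than 8.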

Other observations

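The tests of more lower than higher genes and of the genome around Apoe were chosen only after their results were seen. Several lists had members that passed in the knockout although the list did not. Over all genes 535 of 10401 were higher and 2061 lower (19.8% lower), so member counts near these shares, here and in the next paragraph, do not set a list apart. LXR targets had 2 of 18 higher and 5 lower (camera adjusted p = 0.730), with the cholesterol exporter Abcg1 up from 171 ± 25.4 (SD, n = 7) to 379 ± 37.0 (SD, n = 4) and the desaturase Scd1 down from 90.8 ± 32.8 to 0.891 ± 1.78 (reads in knockout library 2 alone). Lipid droplet and fatty acid genes had 4 of 28 higher and 10 lower (adjusted p = 0.484), among them Fabp3, at least 340-fold lower. TGF-beta signalling had 3 of 22 higher and 8 lower (adjusted p = 0.80), with the ligand Tgfb2 65.6-fold lower (reads in knockout library 1 alone, −8.28 to −6.79 on the log2 scale with a library left out) and the receptor Tgfbr2 1.96-fold higher. Complement had 1 of 14 higher, C1qc from 5053 ± 242 to 8133 ± 580, and 7 lower, including the inhibitor Cd59a (adjusted p = 0.556). Phagocytosis genes had 5 of 27 higher and 9 lower (adjusted p = 0.920), with the receptors Timd4 and Tyro3 at least 172-fold and 141-fold lower. Matrix genes had 1 of 23 higher and 11 lower (adjusted p = 0.139), with the inhibitor Timp3 22.6-fold lower. MHC class II genes had 3 of 13 higher and 3 lower (adjusted p = 0.379), with H2-Aa down from 369 ± 162 to 44.8 ± 15.4 and 28.9 in wild-type library 8.

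Inflammatory genes had 1 of 34 higher and 9 lower in the knockout (camera adjusted p = 0.520), and interferon-response genes 1 of 32 higher and 2 lower (adjusted p = 0.203, and 0.639 with an estimated correlation), or 5 higher and 1 lower under quantile rescaling, which turned their median from −0.20 to 0.54 and made the list pass (camera adjusted p = 0.0443). Quantile rescaling also made the matrix (0.0303), glycolysis (0.0110) and Nrf2 (0.0190) lists pass as lower. Camera with an estimated correlation, run on the values as deposited, gave these lists adjusted p of 0.726, 0.685 and 0.726. Glycolysis had 1 of 25 higher and 9 lower (adjusted p = 0.168), and Nrf2 targets 1 of 24 higher and 7 lower (adjusted p = 0.163). Without wild-type library 8, 14 inflammatory and 12 Nrf2 genes were lower, 4 interferon-response and 4 complement genes were higher, and the Nrf2 list passed as lower (adjusted p = 0.0157). Of 13 neutrophil genes, 2 fell, Mmp8 and Hdc (adjusted p = 0.494), or 1 adjusted over the list alone, 1 with TMM and 0 under quantile rescaling. In edgeR both missed (adjusted p = 0.310 and 0.226), and Hdc was lost in 8 of 11 fits with a library left out, while S100a8, chosen after its value was seen, stood at 1990 ± 950 in the knockout and 1031 ± 443 in the wild type without passing (limma adjusted p = 0.207). After rAPOE, LXR targets had a median of −0.78 with 0 of 13 passing (adjusted p = 0.0833), surface receptors had 3 of 65 higher and 1 lower (adjusted p = 0.607), and disease-associated genes 1 of 30 higher and 1 lower (adjusted p = 0.480). Adjusted over the list alone, 2 LXR targets were higher and 2 lower, 10 surface receptors higher and 6 lower, and 4 disease-associated genes higher and 5 lower. Of 49 neighbours of Apoe, 2 were higher and 11 lower in the knockout, and 0 of 33 passed after rAPOE. The Y-linked gene measured in the genotype table was lower in the knockout, Xist was higher (0.85, SE 0.26), and 0 of 4 Y-linked genes passed after rAPOE.

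Other splits of the same libraries were counted for each comparison. Of 100 splits of the genotype libraries, 1, the real one, gave as many genes (2596, highest other 0). As many lists came from 11 of them (16, highest other 20), so for the number of lists chance cannot be excluded. Each other split puts wild-type and knockout libraries together in a group, and these differ in reads and detected genes, which widens the spread. The gene count thus shows that the groups of libraries differ and not why, and it takes the libraries as separate samples. Of 100 splits of the injection libraries, 1 gave as many genes (34, highest other 5) and 2 as many lists (11, highest other 11), the real split among them. A random split of these libraries thus seldom reached these counts, if they are separate samples.

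A hypothesis for the 2061 lower against 535 higher genes is that knockout libraries held fewer distinct molecules, which may turn low genes to 0. Lower genes made up 97.4% of those passing at a mean of 10 to 50, 68.1% at 50 to 500 and 34.3% at 500 or more, a gap of 63.2 percentage points. The hypothesis foretold such a gap, but the gap cannot decide for it. The mean was taken over all libraries of the table, so a gene near 0 in the knockout falls into a lower bin. RNA of other cells in the wild-type libraries may give the same gap. Another hypothesis is that genome carried along around Apoe from the strain in which it was targeted may give the differences near it. Within 10 Mb of Apoe 30 of 151 genes passed, against 2556 of 10185 elsewhere, a ratio of 0.792 (Fisher's exact test, p = 0.156). Passing genes were thus not in excess near Apoe. With 25.1% of the genes elsewhere passing, a few carried-along genes would hardly raise this ratio, so the test cannot exclude them.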
